A study of Pimephales promelas with 53 samples.

How the data were processed

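Ovary RNA of 53 single adult female fathead minnows (Pimephales promelas) was measured on 1-colour 60-mer oligonucleotide arrays, 1 fish per array. Fish had been held for 4 days in mobile exposure units with water from upstream of a wastewater outfall, the effluent itself, or downstream water, at each of 3 sites called E, H and R. The 9 groups of site by location held 6 fish each, except the downstream group of site E with 5. Per the labels, sites H and R received a continuous flow of water and site E had its water renewed in batches. The sample titles of site E name 24 hours and those of H and R 96 hours, while the source descriptions state 4 days for all. Fish of a group shared their exposure, so the spread between fish covers differences between animals within 1 exposure and not between repeated exposures. Per the labels, 1 µg of total RNA per fish entered the labelling reaction.

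The authors scanned the arrays and extracted each spot with Agilent Feature Extraction 10.7.3.1. Per the file headers the scanner files hold intensity values on a linear scale, of which the processed signal (background removed), the mean signal, the background signal and the flags for detection, saturation and outlying pixels were used. The deposited series table holds log2 values. Set against the scanner files, the group mean of each probe in that table equalled the group mean of log2 mean signal to within 4.5e-09, and Fastlo run within each of the 9 groups came within a median of 0.0443 of its values, against 0.831 for Fastlo over all arrays together. The authors' values are thus scaled within groups and not between them, and group medians ran from 6.86 (site R upstream) to 9.70 (site H downstream). The table was used only as an alternative.

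Each array carried 15208 probes besides control spots. None came with a gene symbol or name in the files: 11862 were labelled by an assembled contig, 3309 by a sequence number and 37 by a clone. The reference table pairs symbols with locus tags and accessions and holds none of these labels, so the gene lists fixed before the data were examined could not be matched, and no list test was run. Probes are given by the identifier of the array design.

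Processed signals at or under 1 were set to 1 and taken to log2. The 1274 spots with outlier flags, of 806024, were left out and saturated spots kept. Arrays were normalized together by Fastlo, as limma's fast cyclic loess (limma 3.58.1, R 4.3.3). The 15089 probes well above background on at least 5 arrays were tested. A linear model with a mean per group was fitted to all 53 arrays in limma (lmFit and eBayes, two-sided moderated tests), with Benjamini-Hochberg adjustment over probes and a threshold of 0.05. Differences between sites in the change from upstream, and differences between upstream fish, were tested with limma's F test on 2 degrees of freedom. A probe not well above background on any array of a group would be given as a bound; the printed probes that passed a test needed none.

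For each comparison the probes to name were set before the data were examined: the 12 largest increases and 12 largest decreases past the threshold, 5 of each for effluent minus downstream, or the 5 smallest p where none passed. As no probe has a gene name, at most 2 that rose and 2 that fell are printed. The array of site R downstream replicate 2 had almost no signal, with a median processed signal of 2.79 and 3.05% of probes well above background. The count of called probes in each comparison is therefore also given for the other 52 arrays normalized without it. That choice was made after the data were seen, and values of single probes come from the fit of 52 arrays.

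Other settings were 75th percentile scaling, quantile normalization, normexp background correction with an offset of 50, no detection filter, detection on at least 27 arrays, each site normalized and fitted alone, the authors' table, replicate number or slide as a block, array weights, and each fish left out in turn. Arrays lay on 21 slides scanned on 2 days. Replicate numbers were not treated as pairs. Arrays of different groups on the same slide deviated together, with a median correlation of 0.245 over 45 pairs of arrays, against -0.0125 on other slides of the same scan day.

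The procedure was tested on simulated data with the real means and spreads and 200 changed probes per site. At site E it recovered 59.1% of 4-fold changes, 16.4% of 2-fold changes and 1.49% of 1.5-fold changes, with 3 false calls among 54. At sites H and R, 62.1% and 66.7% of 4-fold changes were recovered. The noise was drawn for each probe on its own, without normalization or slide effects, so these false calls give no rate for the real arrays. The number of arrays limits the precision. Correlations of changes were taken across probes, which are not independent replicates.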

Results

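A total of 53 ovary transcript profiles were obtained from female fathead minnows exposed at 3 sites to upstream water, effluent or downstream water, with 6 fish per group and 5 in the downstream group of site E. The series set out to compare transcript responses along effluent gradients at different sites. Without the array of site R downstream replicate 2, which had almost no signal, between 60.3% and 99.3% of probes were well above background. Arrays of site R were dimmer than the others. Their median processed signal ranged from 26.0 to 184.5 in upstream fish, from 48.0 to 254.7 in effluent fish and from 174.7 to 320.6 in downstream fish with signal, while arrays of sites E and H ranged from 288.0 to 1729.

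**Figure D1:**
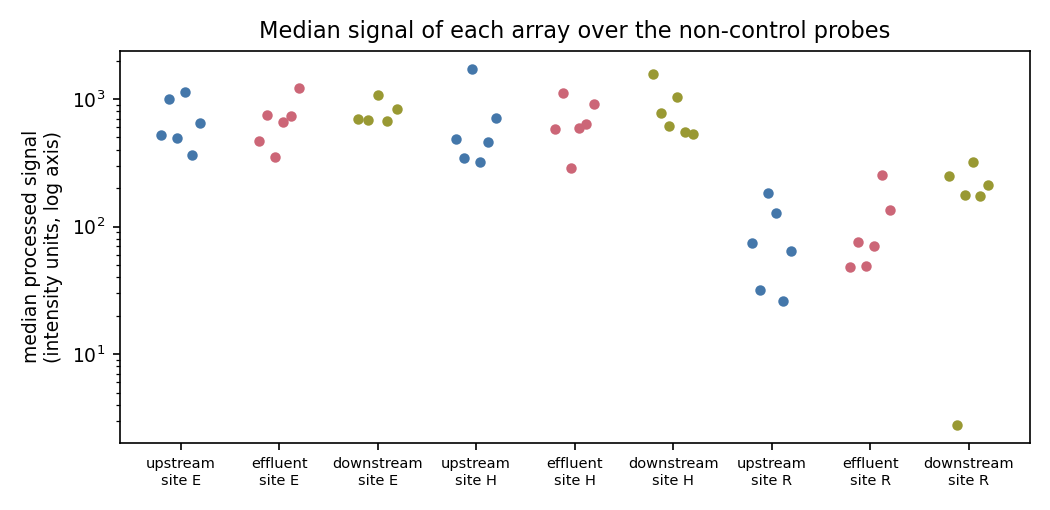
Median processed signal (intensity units, log axis) of each of the 53 arrays by group, 1 point per fish. Arrays of site R lie at or below 320.6 and the failed array at 2.79.

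At site E, effluent fish differed from upstream fish by 1 probe of the 15089 tested. UF_Ppr_AF_117931 (60-mer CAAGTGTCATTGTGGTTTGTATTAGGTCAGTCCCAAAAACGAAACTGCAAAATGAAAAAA) was higher in effluent fish, at a log2 signal of 8.11 ± 0.92 (SD, n = 6) against 4.44 ± 1.102 (n = 6) upstream. The log2 change was 3.67 ± 0.62 (SE; limma adjusted p = 0.00661), and all 6 effluent fish lay above every upstream fish. The call was lost (0 probes) with 75th percentile scaling, with quantile normalization and with site E normalized and fitted alone. It was also lost without upstream replicate 6, which left 0 probes, and 2 probes passed without upstream replicate 4. The 52 arrays also gave 1 probe. Unadjusted p was under 0.05 for 711 probes, and for 749 in the 52 arrays. As many probes or more were called in 6 of 100 splits of these fish.

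At site H, limma called 0 probes between effluent and upstream fish, with 652 probes at an unadjusted p under 0.05, and 0 in the 52 arrays, with 682. The probe with the smallest p, UF_Ppr_AF_111859, measured 8.01 ± 0.58 (SD, n = 6) in effluent fish and 5.54 ± 0.93 (n = 6) upstream, and did not pass (limma adjusted p = 0.294). Downstream and upstream fish of sites E and H gave 0 called probes in limma at either site, with 817 and 433 probes at an unadjusted p under 0.05, and 0 in the 52 arrays, with 823 and 450. At site E, 1 probe passed without downstream replicate 1 and 1 without upstream replicate 6. The smallest p at site E belonged to UF_Ppr_AF_106896, at 4.96 ± 1.86 (SD, n = 5) downstream and 8.07 ± 1.23 (n = 6) upstream, which did not pass (limma adjusted p = 0.0555). Downstream fish of site E compared within the second scan day alone, 2 fish against 3, gave 33 called probes, and within the first scan day, 3 against 3, gave 0. Effluent and downstream fish also gave 0 called probes in limma at E and at H, with 434 and 580 probes at an unadjusted p under 0.05, and 0 in the 52 arrays, with 434 and 585. At E, 1 probe passed without downstream replicate 1, 1 without downstream replicate 2 and 2 without effluent replicate 5.

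At site R, 415 probes differed between effluent and upstream fish, 261 higher and 154 lower in effluent fish, and 475 in the 52 arrays (294 higher, 181 lower). With quantile normalization there were 56 (34 higher, 22 lower) and with 75th percentile scaling 135 (72 higher, 63 lower). UF_Ppr_AF_103460 (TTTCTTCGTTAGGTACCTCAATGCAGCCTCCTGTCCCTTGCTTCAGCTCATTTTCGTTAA) was among the largest increases, at 14.99 ± 0.95 (SD, n = 6) in effluent fish and 12.45 ± 1.498 (n = 6) upstream, a log2 change of 2.54 ± 0.40 (SE; limma adjusted p = 0.000226). Its level in upstream fish of E and H was 15.57 ± 0.61 and 15.71 ± 0.39. The first-ranked increase, UF_Ppr_AF_109168, rested on few fish: the group mean was 9.97 ± 4.14 in effluent fish against 6.92 ± 1.40 upstream, and 2 of 6 effluent fish exceeded all upstream fish. The spot was saturated on 1 effluent array and well above background on 3 of the 6 upstream arrays. The largest decrease was UF_Ppr_AF_111542 (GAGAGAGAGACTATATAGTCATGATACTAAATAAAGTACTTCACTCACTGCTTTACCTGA), at 11.99 ± 1.49 against 14.98 ± 1.53 (log2 change -2.99 ± 0.54, SE; limma adjusted p = 0.00115). UF_Ppr_AF_118499 fell from 9.34 ± 1.63 to 6.38 ± 1.66.

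The largest decreases of site R shared a sequence feature, chosen after their values were seen. A run of alternating G and A of at least 8 bases stood in 11 of the 12 largest decreases and in 0 of the 12 largest increases in effluent fish. It stood in 12 of the 12 largest decreases and in 0 of the 12 largest increases in downstream fish. Of the 15089 tested probes, 71 had such a run. All 16 probes with a run of 10 bases or more were lower in downstream than in upstream fish of site R past the threshold. Their array medians averaged 14.36 ± 1.34 (SD, n = 6) in upstream fish, 11.68 ± 0.96 (n = 6) in effluent fish and 10.92 ± 0.40 (n = 5) in downstream fish, and between 7.15 and 8.03 in the groups of E and H.

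Downstream and upstream fish of site R differed in 2779 probes, 1406 higher and 1373 lower in downstream fish, and in 2405 probes of the 52 arrays (1083 higher, 1322 lower). Changes over 2-fold made up 1501 of the 2405. The split of the calls depended on the scaling in fits that held the failed array, as the fit with 2779 probes did. There, 75th percentile scaling gave 2425 higher and 1453 lower probes, and quantile normalization 642 higher and 997 lower. On the failed array the median and 75th percentile of processed signal were close, at 2.79 and 3.02. How far this array shaped these splits was not tested. UF_Ppr_AF_103460 again rose, to 15.42 ± 0.34 (SD, n = 5) from 12.45 ± 1.498 (n = 6), a log2 change of 2.97 ± 0.42 (SE; limma adjusted p = 6.94e-06), with all 5 downstream fish above every upstream fish. UF_Ppr_AF_112420 measured 12.97 ± 4.02 downstream and 8.79 ± 0.64 upstream (limma adjusted p = 0.0263), and 4 of 5 downstream fish exceeded all upstream fish. Of those 4, replicate 4 measured 9.79, close to the highest upstream fish at 9.265, and the others lay between 15.25 and 16.53. This probe also had separate high and low fish at every site, with 10 of 52 fish high, which made up 17.6%, 16.7% and 23.5% of those at E, H and R. The decreases UF_Ppr_AF_104369 and UF_Ppr_AF_102367, both with a GA run of 11 bases, had log2 changes of -3.97 ± 0.65 (SE) and -3.80 ± 0.59. Of the 1322 lower probes, 1214 had no GA run longer than 5 bases.

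**Figure D2:**
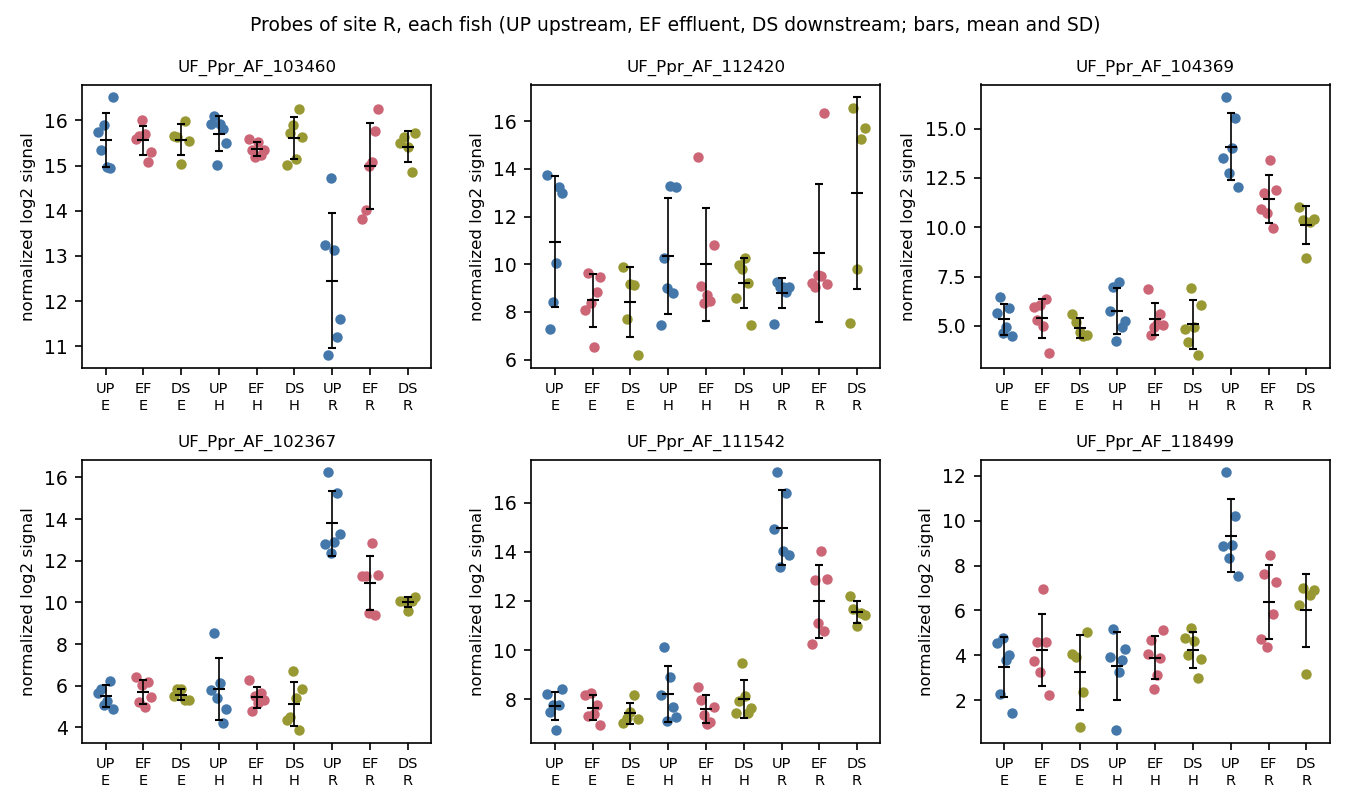
Normalized log2 signal of 6 probes named for site R in each of the 52 fish with signal, by location and site; bars show mean and SD. UF_Ppr_AF_104369, UF_Ppr_AF_102367, UF_Ppr_AF_111542 and UF_Ppr_AF_118499 are highest in upstream fish of site R.

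Most probes called in effluent fish of site R were also called in downstream fish, while most of those called in downstream fish were not called in effluent fish. In the 52 arrays, 256 of the 294 probes higher in effluent fish were among the 1083 higher in downstream fish, against 21.1 if the sets were independent, and 162 of the 181 lower probes were among the 1322 lower there, against 15.9. No probe was called in opposite directions (0 of them). The shared upstream fish raise such overlap. In all 53 arrays, across probes, the 2 changes had Pearson r = 0.69 and Spearman rho = 0.68 at site R. Unchanged groups simulated with a shared upstream mean gave a median r of 0.50. The simulation drew each probe on its own, while real probes vary together, so it gives a level and no test. The jackknife SE of r over fish was 0.168 at R, 0.18 at E and 0.228 at H. With 75th percentile scaling, which also held the failed array, r at R was 0.36. The covariance of the 2 changes at R was 0.315, against 0.135 simulated. With the upstream fish divided 3 and 3 between the comparisons, the median r was 0.36 (range 0.076 to 0.46 over 20 divisions). At site E, r was 0.62 (rho 0.57), against 0.48 simulated and 0.18 with divided upstream fish. At site H, r was 0.49 (rho 0.45), against 0.50 and -0.11. The covariances were 0.180 at E and 0.117 at H, against 0.112 and 0.145 simulated.

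Direct comparison of effluent with downstream fish at site R gave 34 probes, 25 higher and 9 lower in effluent fish, and 20 in the 52 arrays. UF_Ppr_AF_114806 was the largest increase, at 11.72 ± 2.07 (SD, n = 6) against 7.27 ± 0.76 (n = 5; limma adjusted p = 0.0223). High and low fish of this probe also occurred within groups. Effluent replicate 5 measured 7.64, and upstream replicates 3 and 4 of R measured 6.99 and 7.18 while the other upstream fish lay between 11.45 and 12.43. UF_Ppr_AF_101941 was lower, at 9.77 ± 0.57 against 11.19 ± 0.71 (limma adjusted p = 0.0498). With 75th percentile scaling, which held the failed array in the downstream group, 438 probes were higher and 2451 lower in effluent fish. The median log2 change over all probes was -0.90 there, and 18 of the 34 probes were called in the same direction. On the failed array the median and 75th percentile of processed signal were close, at 2.79 and 3.02. How much of the -0.90 and of these calls comes from that array was not tested. The count also depended on single fish: it was 0, 52, 1, 2, 293 and 54 without effluent replicates 1 to 6 in turn, and 102, 17 and 22 without downstream replicates 1, 3 and 4.

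Limits apply to the counts of site R. With slide as a block, the counts were 162 for effluent minus upstream, 1553 for downstream minus upstream and 0 for effluent minus downstream, and in the 52 arrays 130, 643 and 0. In the authors' table, scaled within groups, the 3 comparisons gave 2702 higher and 40 lower, 3449 higher and 1137 lower, and 2087 higher and 322 lower probes. Within the first scan day, 4 downstream fish against 3 upstream fish gave 314 probes and 3 effluent against 3 upstream fish gave 1; within the second, 3 effluent against 3 upstream fish gave 0. The second day held 1 downstream fish with signal. With site R normalized and fitted alone the counts were 1 for effluent minus upstream and 549 for downstream minus upstream. Without single fish the effluent minus upstream count lay between 152, without upstream replicate 5, and 668, without upstream replicate 3; it was 165, 219, 203 and 171 without upstream replicates 2 and 6 and effluent replicates 3 and 5. With array brightness as a covariate in the 52 arrays, downstream minus upstream gave 577 probes.

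**Figure D3:**
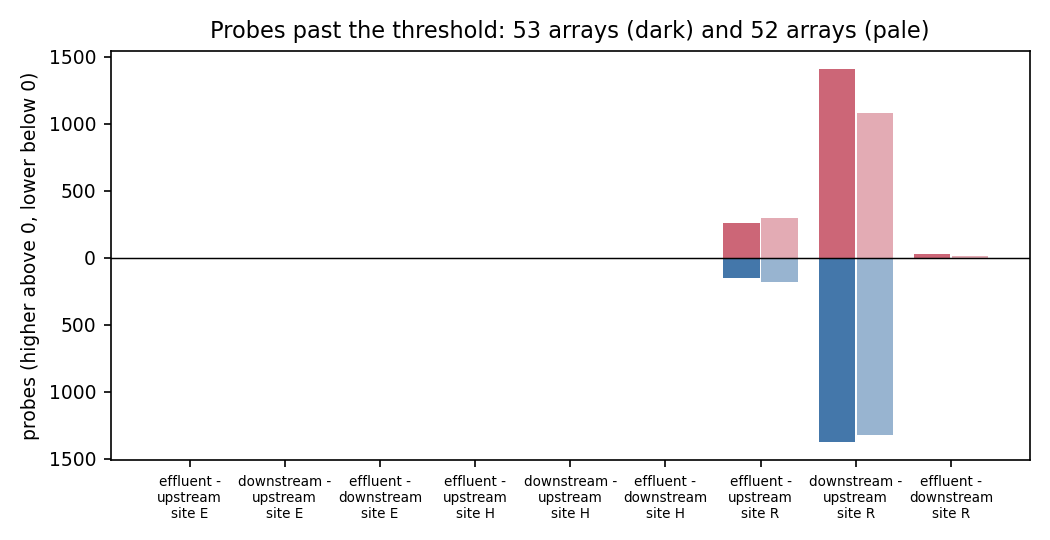
Number of probes past the threshold in each comparison, higher in the first group above 0 and lower below 0, for 53 arrays (dark) and 52 arrays (pale). Counts reach 1406 and 1373 for downstream minus upstream at site R and are 0 or 1 at E and H.

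The differences between sites were themselves tested. The change from upstream to downstream differed between sites for 628 probes (limma F test), and for 370 in the 52 arrays. It was 1106 without H upstream replicate 2, and 301 and 321 without R upstream replicates 5 and 2. It was 367 with 75th percentile scaling, 21 with quantile normalization, 284 with slide as a block, 1509 in the authors' table and, in the 52 arrays, 61 with array brightness as a covariate. For UF_Ppr_AF_100675 it was 1.66 ± 0.19 (log2, SE) at R, -0.015 ± 0.19 at E and 0.090 ± 0.18 at H (limma adjusted p = 0.000512). For UF_Ppr_AF_110916, whose GA run has 9 bases, it was -4.02 ± 0.52 at R, -0.25 ± 0.52 at E and 0.24 ± 0.50 at H. The change from upstream to effluent differed for 2 probes, and for 11 in the 52 arrays. Without single fish it ranged from 1 to 36, the latter without R upstream replicate 3, and it was 0 with quantile normalization and 1555 in the authors' table. UF_Ppr_AF_111391 (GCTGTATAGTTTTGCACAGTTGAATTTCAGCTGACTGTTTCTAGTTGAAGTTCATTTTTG) changed by 1.86 ± 0.25 at R, against 0.094 ± 0.25 at E and -0.34 ± 0.25 at H (limma adjusted p = 0.00274). UF_Ppr_AF_114986 changed by -1.35 ± 0.25 at R, against 0.38 ± 0.25 and 0.30 ± 0.25. For each of these probes upstream fish of R lay apart from those of E and H, and the change at R went toward them. Upstream means at E, H and R were 12.57, 12.49 and 10.25 for UF_Ppr_AF_100675 and 6.11, 5.79 and 12.33 for UF_Ppr_AF_110916. They were 12.47, 12.99 and 10.85 for UF_Ppr_AF_111391 and 10.98, 10.72 and 12.36 for UF_Ppr_AF_114986. Effluent changes of different sites showed no relation across probes beyond that of shuffled fish. Pearson r (rho) in the 52 arrays was 0.00021 (0.0049) for E and H, 0.031 (-0.014) for E and R, and 0.094 (0.11) for H and R, and 100, 82 and 51 of 100 shuffles of fish within sites gave an r as far from 0.

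Upstream fish, which received no effluent, differed between the 3 sites in 6937 probes (limma F test), and in 6991 in the 52 arrays. The count was 4345 with replicate number as a block, 13886 in the authors' table and, in the 52 arrays, 3786 with array brightness as a covariate. Between E and H, limma called 0 probes, whereas 7042 differed between E and R and 6783 between H and R in the 52 arrays. Of these, 5603 and 5253 differed by over 2-fold. UF_Ppr_AF_118494 (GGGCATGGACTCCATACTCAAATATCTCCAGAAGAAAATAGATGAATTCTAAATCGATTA) measured 9.56 ± 0.30, 9.95 ± 0.55 and 13.47 ± 0.58 (SD, n = 6 each) in upstream fish of E, H and R. UF_Ppr_AF_112510 measured 6.54 ± 0.39, 7.41 ± 1.28 and 12.53 ± 0.61. Both differences exceeded the spread between fish. Site goes with place and date, so these are differences between sets of fish.

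Fish of site R were also set out by location along the difference between sites. Each fish was placed on the line from the mean profile of R (0) to that of E and H (1), with its own group kept out of the line. Each group of R thus has its own 0, set by the other groups of R, which moves the groups apart. The correlation of the effluent change with a site difference free of its fish was 0.274, within that of shuffled fish (-0.282 to 0.307). Fish of R lay at -0.19 ± 0.062 (SD, n = 6) upstream, 0.079 ± 0.088 (n = 6) in effluent and 0.29 ± 0.036 (n = 5) downstream. The lowest downstream fish lay at 0.248 and the highest upstream fish at -0.0987, each on the line of its own group, so their distance is not on a common scale. The other fish lay between 0.835 and 1.14, apart from H upstream replicate 2 at 0.25. Leaving out that fish and the failed array gave 0 called probes between effluent and upstream fish at site H and 0 between downstream and upstream fish.

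**Figure D4:**
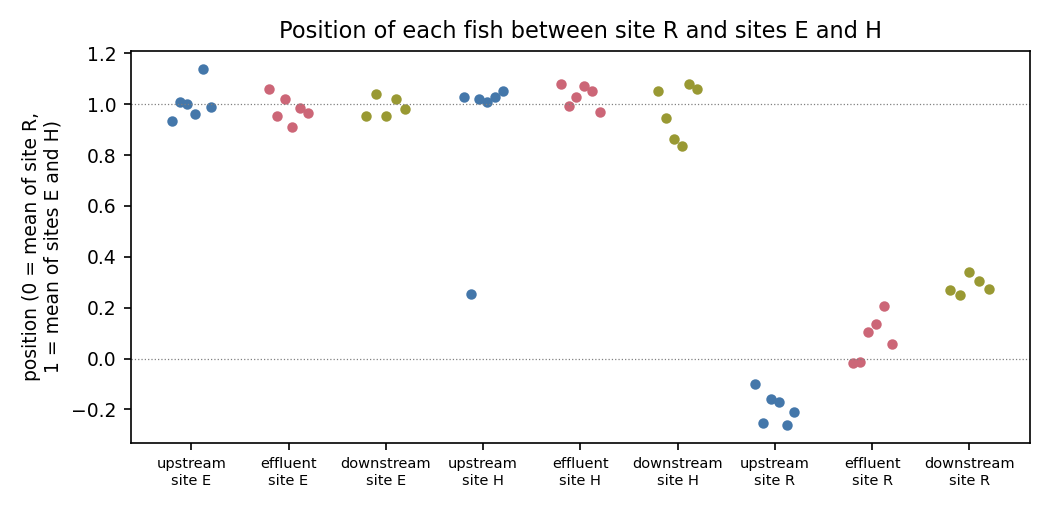
Position of each of 52 fish between the mean profile of site R (0) and of sites E and H (1), 1 point per fish. The own group is excluded, so each group has its own line. Upstream fish of R lie lowest, from -0.261 to -0.0987, and 1 upstream fish of H lies at 0.252.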

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

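Tests on the difference between sites as the line of movement at site R, on a swapped fish and on splits with slide as a block were chosen after the result was seen, as were the fits that leave out an array and the condition that a ratio stay above the limit with single fish left out. Of 73 checks on groups of fish, 10 found a fish far from the others, where chance alone would give about 1 in 20, here 3.65. The checks overlap, and many concern probes chosen for large changes. Several of the 10 are the failed array, so the excess over 3.65 is not a count of separate fish.

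The first pattern is that fish of site R differ between locations: of 100 splits of the same fish, 1 (the real one) reached the count for downstream minus upstream (real 2795 with missing spots filled, highest other 1667), and 2 and 3 reached those for effluent minus upstream (422, highest other 590) and effluent minus downstream (35, highest other 57). These splits used all 53 arrays, with the failed array in the downstream group. None was drawn in the 52 arrays without slide as a block. With slide as a block in every split, 1 reached the downstream minus upstream count (real 1575, highest other 404), and in the 52 arrays 1 (669 and 154). For effluent minus upstream 1 reached it (real 170, highest other 7), and in the 52 arrays 3 (130 and 438). Chance among these fish is thus unlikely for downstream minus upstream. It is left open for effluent minus upstream, where another split gave more probes than the real one, and for effluent minus downstream, which slide as a block took to 0. Chance between exposures was not tested, as fish of a group shared theirs. With slide as a block the called changes kept a median of 0.906 of their size downstream and 1.03 in effluent. No slide held both upstream and downstream fish of R with signal, and effluent and upstream fish shared only slide 19. The block thus compares them mostly through other groups, so slide cannot be told apart from location. Array brightness as a covariate left 0.961 of the effluent changes, which argues against it there, but 0.753 of the downstream changes (0.730 to 0.796 with single fish left out), so for downstream fish, which were brighter as a group, it cannot be told apart from location. The changes may follow the same line as the difference between sites. The correlation across probes with the difference of E and H fish from the R group in neither arm was 0.476 for downstream (shuffled fish -0.435 to 0.39). It was 0.274 for effluent (-0.282 to 0.307). This stays open, along with location itself, slide, RNA quality and ovary condition.

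The second pattern is that fish of site R stand apart from those of E and H, with H upstream replicate 2 among them. This fish was far from its group, at a position of 0.252 where the other 5 lay between 1.01 and 1.05, and its deviation from them correlated across probes with the difference between R and E upstream fish (r = 0.516). The slope of position on brightness within groups gives 0.0239 of the distance between sites (2 SE range -0.0543 to 0.102). Brightness goes almost wholly with site, so that slope is carried past the range of most groups and cannot settle the question. Brightness as a covariate also lowered the count between upstream fish, as given above. For H upstream replicate 2, a median signal of 345.7 argues against brightness, as it was not the dimmest of H (288.0). A swap with a fish of R would need a partner near E and H, and the highest of the 17 fish of R with signal lay at 0.339; the failed array could not be placed, and a mix-up with a sample outside these arrays cannot be excluded. Place, date and the stock or condition of the fish go with site and stay open as untested.

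The third pattern is that calls from the authors' table at site R go mostly 1 way, with 2702 of 2742 higher in effluent than in upstream fish. The cause may be its scaling within groups: Fastlo of the same mean signals over all arrays lowered the share that is higher by 42.6 points, to 55.9%. As that fit also took no background off, the mean signals themselves do not produce the imbalance. No biological explanation was tested.

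Other results far from their group, all from the 53 arrays normalized together, were the 3.05% of probes well above background and the log2 median signal of 1.48 in site R downstream replicate 2 (the others 83.3% to 95.3% and 7.45 to 8.32). The same array gave 19.59 for UF_Ppr_AF_103460, 7.50 for UF_Ppr_AF_102367 and 16.93 for UF_Ppr_AF_110417 on the normalized log2 scale. UF_Ppr_AF_109168 was 18.19 in R effluent replicate 1 against 7.50 to 9.19 in the others. UF_Ppr_AF_112420 was 7.37 in R upstream replicate 1, UF_Ppr_AF_114682 was 9.37 in E downstream replicate 2, and UF_Ppr_AF_114806 was 7.49 in R effluent replicate 5.

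The change from upstream differed between sites for 628 probes downstream and 2 probes in effluent. Of 100 splits within sites, 1 and 7 gave as many (real 662 and 2, highest others 355 and 205). With slide as a block the first was reached by 1 of 100 splits (real 287, highest other 19), and in the 52 arrays by 1 (167 and 30). Chance among these fish is thus unlikely for the first and left open for the second. Chance among these fish is also unlikely for the 6937 probes between upstream fish (1 of 100 splits, real 6952, highest other 4868). With slide as a block, 1 split reached that count (7485 and 4207). For the counts of site E, 6 of 100 splits reached that of effluent minus upstream (real 1, highest other 2), and 100 of 100 reached each count of 0 there (highest others 1 and 1). At site H the counts of 0 were reached by 100 of 100 splits, with highest others of 87 for effluent minus upstream, 12 for downstream minus upstream and 14 for effluent minus downstream. The splits with 87 and 205 probes may point to a structure among the fish, and whether a single fish or a shared slide makes them was not tested.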

How the results depend on the processing

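The fits without the failed array, alone or with a further change, were chosen after the data were seen. The other settings held that array, 75th percentile scaling and quantile normalization among them, except where it was the fish left out. Counts are given in the order effluent minus upstream, downstream minus upstream and effluent minus downstream, or as stated. At site R, 75th percentile scaling gave 135, 3878 and 2889 probes, quantile normalization 56, 1639 and 6, each site normalized and fitted alone 1, 549 and 0, the authors' values 2742, 4586 and 2409, slide as a block 162, 1553 and 0, and array weights 453, 2339 and 262. The replicate number as a block gave 267, 2593 and 6; no comparison has all same-numbered pairs over a correlation of 0.1, so the fish were not paired, though at site R downstream minus upstream had 3 of 5 pairs over it (range -0.13 to 0.31, median 0.103 against -0.0624 in other pairs) and effluent minus upstream 2 of 6 (range -0.30 to 0.36). Without the failed array the counts at R were 475, 2405 and 20; with site R alone 1, 724 and 0; with scan day as a block 545, 2132 and 9; with slide as a block 130, 643 and 0; with brightness as a covariate 405, 577 and 1. At site E, effluent minus upstream gave 0 probes with 75th percentile scaling, 0 with quantile normalization, 0 fitted alone and 2 in the authors' table, where downstream minus upstream gave 2; effluent minus downstream gave 1 with normexp, 1 fitted alone and 3 with array weights. At site H the authors' table gave 3, 10 and 87 probes, and the replicate block 1 for effluent minus downstream. The effluent change differed between sites for 1 probe with 75th percentile scaling, 0 with quantile normalization, 15 with normexp, 8 with detection on at least 27 arrays, 1555 in the authors' table, 1 with the replicate block, 1 with slide, 18 with array weights, 11 without the failed array, and then 23 with scan day, 1 with slide, 15 with brightness and 36 without H upstream replicate 2. The downstream change differed for 367 with 75th percentile scaling, 21 with quantile normalization, 1509 in the authors' table, 286 with the replicate block, 284 with slide, 370 without the failed array, and then 162 with slide and 61 with brightness. Upstream fish differed between sites in 13886 probes in the authors' table, 4345 with the replicate block and 3786 with brightness. The correlation of effluent and downstream changes at R was 0.362 with 75th percentile scaling, failed array included. With each fish left out in turn, effluent minus upstream ranged from 0 to 2 at E, 0 to 0 at H and 152 to 668 at R; downstream minus upstream from 0 to 1, 0 to 0 and 2135 to 3080; effluent minus downstream from 0 to 2, 0 to 0 and 0 to 293; the effluent change differing between sites from 1 to 36, the downstream change from 301 to 1106, and upstream fish from 6477 to 7269. The cause was not tested; the authors' table holds no scaling between groups, and fits with a block or fewer fish have fewer degrees of freedom. Changes of single named probes kept their side of the threshold in 231 of 272 fits with a fish left out (36 weaker, 5 stronger) and in 287 of 355 others (64 weaker, 4 stronger), and 0 reversed. The gene lists were not run, as no probe has a gene name. The dim arrays of site R limit its probes near background, and within the second scan day most comparisons had too few fish to test.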

Other observations

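The tests of GA runs were chosen after the result was seen. Probes with runs of alternating G and A formed a group of their own in site R. The median log2 difference of upstream fish of R from the mean of E and H was 0.27 for the 406 probes with runs of 6 or 7 bases, 1.72 for 55 probes with 8 or 9, and 6.59 for 16 probes with 10 to 16. Runs of C and T showed no such rise, at 0.31, 0.24 and -0.495 for 365, 31 and 9 probes. Before normalization the array medians of the 16 probes still averaged 11.98 on the log2 scale in R upstream fish, against 8.47 in E upstream fish. H upstream replicate 2 measured 10.32 for them, against 7.03 to 8.19 in the other H upstream fish. A candidate explanation is binding of other labelled RNA that carries the complementary run rather than a rise of 16 separate transcripts. The median difference grew by 6.32 from runs of 6 or 7 bases to runs of 10 to 16. The quartiles of the latter lay 4.39 and 7.75 above the median of the former. The origin of such labelled RNA was not tested. Runs of 8 bases or more stood in 27 of the 268 probes over 8-fold higher in R upstream fish and in 0 of the 227 over 8-fold lower, so most probes with such large differences have no such run.

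A total of 26 probes split the fish of every site into a high and a low level with a gap of at least 1.5 on the log2 scale and at least 8 fish on each side, against 2 in normal noise with the same means and spreads. UF_Ppr_AF_112725 (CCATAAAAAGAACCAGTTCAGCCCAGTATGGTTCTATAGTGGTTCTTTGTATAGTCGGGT) measured 5.02 ± 1.14 (SD) in 28 fish and 12.3 ± 0.63 in 24, and the high fish were 58.8%, 38.9% and 41.2% of those at E, H and R. UF_Ppr_AF_118788 (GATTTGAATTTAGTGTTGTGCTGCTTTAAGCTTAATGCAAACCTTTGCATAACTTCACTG) measured 7.20 ± 0.62 in 14 fish and 13.4 ± 0.66 in 38. A state of the ovary shared by fish would make such probes vary together. Their median absolute correlation across fish, group means removed, was 0.105, and its difference from random probes of like signal was -0.0361 (range -0.0714 to -0.00639), which argues against it. Sequence variants between fish could give such levels and were not tested.

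The effluent minus upstream change averaged over sites E and H gave 0 called probes in limma, with 844 at an unadjusted p under 0.05. Downstream changes had an r across probes of 0.25 for E and R, 0.10 for E and H and 0.084 for H and R, which 7, 61 and 50 of 100 shuffles of fish reached in size.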
